A study of Mus musculus with 6 samples.

How the data were processed

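Poly(A) RNA libraries of mouse BMVECs, 6 in all (3 untreated, 3 with processed mouse IL-36β at 100 ng/ml for 24 h) were made with a stranded mRNA kit and sequenced on an Illumina NextSeq, per the labels' protocols. Samples were grouped by their titles, and columns of the series tables were matched to samples by library name. The replicate number in the titles and the letter of the library name disagree for IL-36β replicates 2 and 3 and for untreated replicate 3, so neither was used to pair libraries in the main test. The authors' tables hold 8 further per-library columns, of 4 libraries that match no sample label, and these were not used here.

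The submitters' processing notes name fastp, HISAT2 2.05, StringTie, featureCounts 1.50-p3, DESeq2 1.38.3 and the mouse build GRCm38, without roles or settings; the strand setting of the counting is not given in the sources used here. The authors deposited FPKM for 54532 genes, with gene identifier, symbol, coordinates and length in the same table. The authors also deposited a table of 660 genes with raw counts, normalized counts (a signal scale, counts divided by a size factor per library), log2 fold changes, p-values and adjusted p-values, and a table of enriched gene ontology terms with their p-values. In that table the authors' group means differ by over 1% from the mean of the 3 libraries in 594 genes for IL-36β and 573 for untreated cells, so only its signs, p-values and counts of genes were used.

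The deposited FPKM times gene length gave whole numbers of reads, after a single divisor per library, in 100% of values within 0.01 of a whole number, and these recovered reads equal the deposited counts in all 660 genes that have both. The divisor is the authors' size factor times a constant shared by all libraries, so this FPKM is scaled by size factors and not by each library's total. Recovered reads were 15790499, 19544689 and 15439602 in untreated replicates 1 to 3 and 15180389, 16488697 and 18938592 in IL-36β replicates 1 to 3; the 10 most abundant genes took 7.03 to 8.02% of reads. At a gene length of 1 kb, 1 FPKM corresponds to 15.4 to 20.3 reads. Replicates of a group differed by more than sampling noise (chi-square per degree of freedom of 11 to 40.5), so no library was counted as a duplicate.

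The tests, filters, gene lists, rule for named genes and first set of alternatives were fixed before the data were examined. Because FPKM are not counts, the main test was limma 3.58.1 (R 4.3.3) with a trended prior on log2(FPKM + 0.5), two-sided, for 12618 genes with an FPKM of at least 0.5 in at least 3 of the 6 libraries, and Benjamini-Hochberg adjusted p under 0.05 was the threshold. Fold changes and their 95% confidence intervals are on the log2(FPKM + 0.5) scale, which understates the change of low genes; levels are means ± SD of FPKM. The test was checked on simulated reads drawn from the real libraries for this comparison, with 200 of 12412 genes changed per run in 5 runs. It called 60.5% of 2-fold and 93.6% of 4-fold changes and 0.1% of unchanged genes. These were 293, 454 and 52 calls. The simulated libraries of a group shared 1 mean per gene, so these shares may not hold for genes that differ between sets of the real libraries.

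Fixed in advance were 31 gene lists: pathways of endothelial inflammation, barrier and vessel function, stress and metabolism, and markers of endothelium and of the other brain cell types a culture could hold. Symbols in the lists matched the table directly or, for 6, through older symbols in the RefSeq gene table. Lists with at least 5 measured members (25) were tested with camera at a preset correlation of 0.01, Benjamini-Hochberg adjusted over these 25; camera with an estimated correlation and fry were alternatives. Named genes were the 8 largest rises and 8 largest falls past the threshold with a mean FPKM of at least 1 in a group, no overlap of groups and no predicted-gene symbol. Added to these were up to 4 members past the threshold per list, or the 2 most abundant members as values where none passed. Last, they were 13 fixed genes: Il1rl2, Il1rap, Cdh5, Cldn5, Ocln, Tjp1, Pecam1, Tek, Angpt2, Icam1, Vcam1, Sele and Plvap. Other genes, among them those named for passing in DESeq2, with the library set as a term or when adjusted over a list alone, were chosen after their values were seen. The result of 1 gene that the rule names is not reported here.

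Alternatives were other pseudocounts, filters and scalings (quantile, median ratio, TPM), robust and weighted fits, protein-coding genes only, blocks by title number and by library letter, and leaving out each library. Added after the data were examined were edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 on the recovered reads, and the library set (letters A and B, or D and E) as a term. The set splits the groups unevenly: A and B hold 2 untreated and 1 IL-36β library, and D and E hold 1 and 2. Within-set values are differences of mean log2 values with no test of their own. The labels give no date or batch.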

Results

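Gene expression was measured by RNA sequencing in primary brain microvascular endothelial cells (BMVECs), the cells that line brain capillaries and form the blood-brain barrier. The cells were grown from brain vessel fragments of C57BL/6J mice, under puromycin selection. They were either left untreated or exposed to processed mouse IL-36β (DEVD mIL-36β in the titles) at 100 ng/ml for 24 h. The titles give no time or vehicle for the untreated cells, so an effect of time in culture cannot be told apart from IL-36β here. The untreated libraries are named A0, B0 and D0, and the IL-36β libraries A24, D24 and E24. If these numbers are hours, every IL-36β library was also taken later than every untreated one. IL-36β is a cytokine of the IL-1 family that signals through the receptor chains encoded by Il1rl2 and Il1rap. There were 3 untreated and 3 IL-36β libraries, with 15180389 to 19544689 reads assigned to genes per library. The labels do not say whether the libraries of a group came from separate animals or cultures, so the p-values measure the spread between these libraries only. The library names carry letters, and the libraries lettered A and B (untreated 1 and 2, IL-36β 1) differed from those lettered D and E (untreated 3, IL-36β 2 and 3) in 220 genes, of which 156 were lower in D and E. For this reason, values within each of these library sets and from a model with the set as a term, chosen after the data were examined, stand beside the pooled values. The sets were picked from these same values. The 220 genes, and p-values and intervals that use the sets, may therefore overstate the evidence.

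The comparison of IL-36β with untreated cells addressed how cultured BMVECs respond to this protein. No group lacked or blocked the IL-36 receptor, so its part in the response was not tested. Transcripts of cytokines, chemokines and NF-κB feedback genes, and of the adhesion genes Icam1 and Sele, were higher with IL-36β. The gene with the largest rise past the threshold was Csf3, which encodes the neutrophil growth factor G-CSF (chromosome 11, 98701263 to 98703629, plus strand, GRCm38). Csf3 rose from 1.25 ± 0.636 to 30.4 ± 13 FPKM (SD, n = 3 per group), a 17.4-fold rise with a 95% confidence interval of 10.0 to 30.3 (limma adjusted p = 0.0179). Within the library sets its rise was 23.2-fold in A and B and 19.0-fold in D and E. Il6, a pleiotropic inflammatory cytokine (chromosome 5, 30013114 to 30019981, plus strand), rose 7.83-fold from 0.292 ± 0.138 to 5.67 ± 0.932 FPKM (limma adjusted p = 0.00633). Cxcl5, a neutrophil chemokine on the same chromosome (90759360 to 90761624), rose 7.99-fold from 0.112 ± 0.116 to 4.68 ± 2.46 FPKM (limma adjusted p = 0.0275). These folds are on the same scale, which understates the change of low genes such as Il6 and Cxcl5, so the ranking depends on it. Over the alternative settings the log2 fold change reached 5.82 for Cxcl5, 4.95 for Csf3 and 4.59 for Il6. Ccl5, a chemokine for T cells and monocytes, rose 3.13-fold, but from 4 reads in all untreated libraries together to 63 reads with IL-36β.

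Of the 22 measured members of the list of inflammatory cytokines and chemokines, 5 rose and none fell over all genes tested, and 19 rose when adjusted over the list alone. The fifth member past the threshold, Cxcl16, rose 2.70-fold; it lies outside the naming rule and was chosen after its values were seen. All 22 fitted fold changes were above 0, with a median log2 fold change of 1.61, and the list stood above the other genes (camera adjusted p = 3.22e-24; adjusted p = 0.182 with an estimated correlation). The median was 1.53 within library set A and B and 1.85 within set D and E. With the set as a term 14 members rose (camera adjusted p = 4.48e-29; adjusted p = 0.0842 with an estimated correlation).

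The list of NF-κB pathway and feedback regulators followed the same direction, with 3 of 24 measured members higher over all genes and 17 higher when adjusted over the list alone (median log2 fold change 0.55; camera adjusted p = 8.68e-17; adjusted p = 0.182 with an estimated correlation). Nfkbia, the inhibitor that retains NF-κB in the cytoplasm, rose 1.89-fold from 90.0 ± 3.02 to 171 ± 13.9 FPKM. Bcl3, a nuclear partner of the p50 subunit, rose 2.67-fold, and Tnip1, which restrains NF-κB with A20, rose 2.45-fold. A model with the set term called 8 members higher.

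Leukocyte adhesion molecules were split. Icam1, the ligand of leukocyte integrins (chromosome 9, 21015985 to 21028817, plus strand), rose 2.91-fold from 56.7 ± 12.2 to 164 ± 11.3 FPKM (95% confidence interval 2.22 to 3.82; limma adjusted p = 0.0284). Sele, which encodes E-selectin (chromosome 1, 164048234 to 164057677), rose 3.11-fold from 1.06 ± 0.270 to 4.36 ± 0.873 FPKM (limma adjusted p = 0.0322). Vcam1 was 46.4 ± 17.9 FPKM in untreated cells and 139 ± 12.3 with IL-36β, and this 3.14-fold difference did not pass the threshold in the pooled limma test (limma adjusted p = 0.112), while DESeq2 called it and limma without untreated replicate 3 gave an adjusted p of 0.0448. With the library set as a term Vcam1 was 3.63-fold higher (95% confidence interval 2.61 to 5.06; limma adjusted p = 0.0151), and it was 2.66-fold higher within set A and B and 4.97-fold higher within set D and E. Of the 13 measured list members 2 rose over all genes and 4 when adjusted over the list alone, while 6 had fitted fold changes below 0 (median log2 fold change 0.15; camera adjusted p = 0.00950; adjusted p = 0.782 with an estimated correlation). This list's call was lost without untreated replicate 3 (camera adjusted p = 0.0554) and without IL-36β replicate 1 (camera adjusted p = 0.0653).

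**Figure D1:**
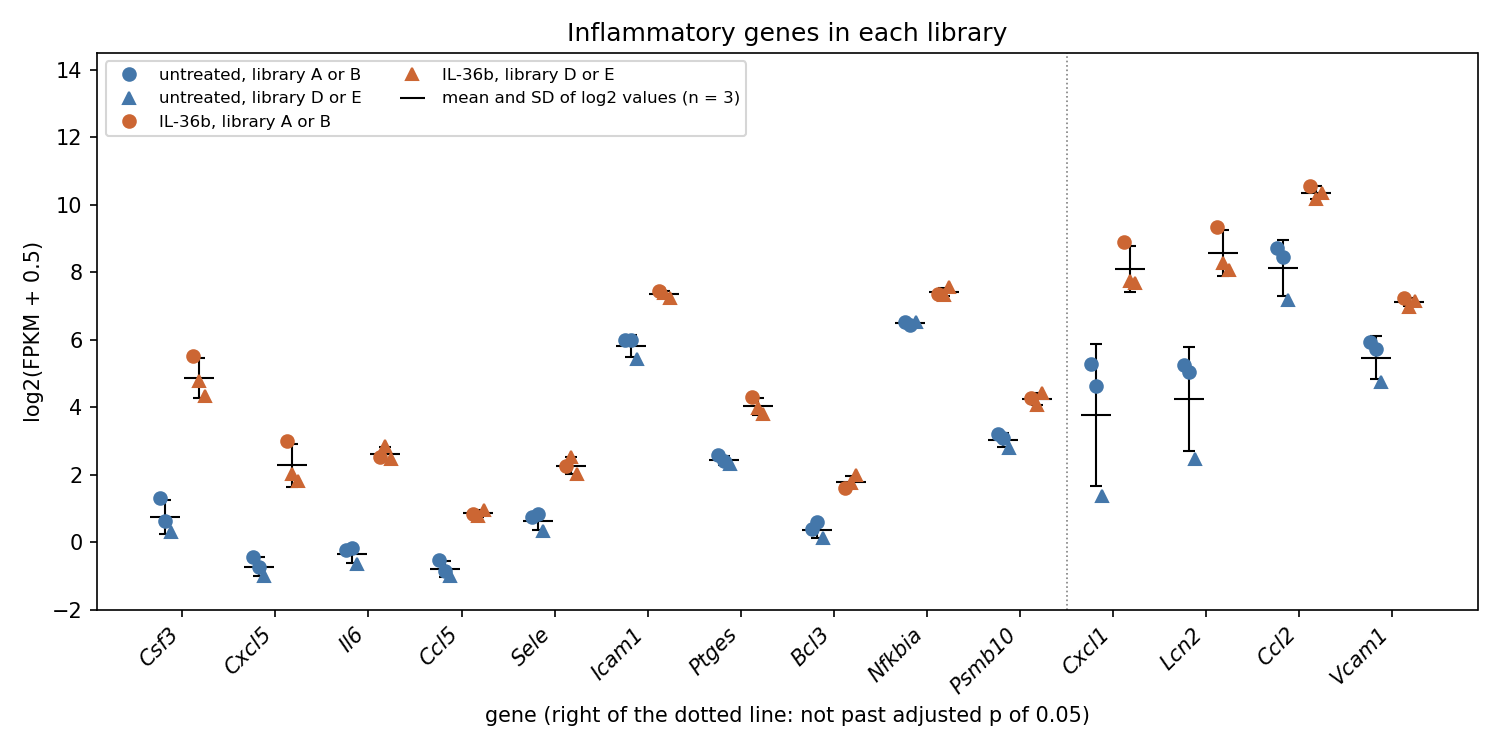
Points are log2(FPKM + 0.5) of 14 inflammatory genes in each of the 6 libraries, with circles for library letters A or B, triangles for D or E, and bars for the mean and SD of 3 libraries. In the 10 genes left of the dotted line every IL-36β library lies above every untreated library; Cxcl1, Lcn2, Ccl2 and Vcam1 on the right did not pass in the pooled limma test, while DESeq2 called all of them.

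In total 23 of 12618 genes tested passed the threshold, 21 higher and 2 lower (limma, Benjamini-Hochberg adjusted p under 0.05), and 1308 had an unadjusted p under 0.05. In each of the 23 genes the 2 groups did not overlap; over all genes tested this was so for 16.2%, where chance gives 10%. Other genes among the 8 largest rises were Neurl3, an E3 ubiquitin ligase gene, 5.81-fold, Icosl, the ligand of the T cell costimulator ICOS, 3.82-fold, and Ptges, prostaglandin E synthase, 3.03-fold. The genes called lower were Mir194-1 (chromosome 1, 185313319 to 185313385) with 11 reads in the untreated and 0 in the IL-36β libraries, and Gm11382 (chromosome 13, 32938513 to 32938691) with 13 and 0 reads. Gm11382 lies outside the naming rule and was chosen after its values were seen. Mir194-1 is a microRNA precursor locus, Gm11382 a pseudogene, and at this depth no fold is given for either.

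The count rested on all 6 libraries: it was 4, 2 and 8 without untreated replicate 1, 2 or 3, and 6, 2 and 4 without IL-36β replicate 1, 2 or 3. In a model with the library set 102 genes passed, 85 higher and 17 lower, and these included all 23; DESeq2 on the recovered reads called 173 genes higher and 96 lower, and edgeR 33 and 4.

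Several of the largest differences missed the threshold in the pooled limma test. Of 17 genes that differed at least 4-fold, 5 passed. The genes named next were chosen after their values were seen. Lcn2, an iron-sequestering acute phase protein, was 24.8 ± 17.4 FPKM in untreated and 410 ± 210 FPKM in IL-36β libraries, a 20.0-fold difference (limma adjusted p = 0.106). Cxcl1, a neutrophil chemokine, differed 20.1-fold (limma adjusted p = 0.183); its untreated libraries stood at 38.5, 24.4 and 2.08 FPKM and its IL-36β libraries at 472, 212 and 203 FPKM. Ccl2, a monocyte chemokine, was 4.71-fold higher, from 307 ± 145 to 1321 ± 171 FPKM (limma adjusted p = 0.107). In the model with the set term Lcn2 was 31.2-fold higher (95% confidence interval 18.8 to 51.7), Cxcl1 34.9-fold (15.5 to 78.7) and Ccl2 5.74-fold (3.81 to 8.64), with limma adjusted p of 0.0026, 0.0116 and 0.0131. DESeq2 on the recovered reads called Lcn2, Cxcl1 and Ccl2 without the set term, and without untreated replicate 3 limma called Ccl2 (adjusted p = 0.0429) but not Lcn2 (0.0520) or Cxcl1 (0.0665). Within set A and B the differences of Lcn2, Cxcl1 and Ccl2 were 18.6-fold, 15.2-fold and 3.87-fold, and within set D and E 52.5-fold, 80.4-fold and 8.49-fold.

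Genes of acute phase and innate defence and of MHC class I antigen presentation were also higher as groups. Of 14 measured members of the acute phase, complement and innate defence list, Ptges rose over all genes and 8 members rose when adjusted over the list alone (median log2 fold change 0.64; camera adjusted p = 3.04e-07; adjusted p = 0.532 with an estimated correlation). In the MHC class I list Psmb10, a subunit of the immunoproteasome, rose 2.33-fold and Tapbp, the peptide-loading chaperone tapasin, rose 1.94-fold. All 22 measured members of that list had fitted fold changes above 0, and 7 rose when adjusted over the list alone (median log2 fold change 0.39; camera adjusted p = 2.38e-08; adjusted p = 0.532 with an estimated correlation). Of the 7 measured genes of MHC class II and costimulation 1 rose, Icosl (camera adjusted p = 0.462).

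Interferon-stimulated genes were higher as a list, with 33 of 36 fitted fold changes above 0 and a median log2 fold change of 0.26 (camera adjusted p = 7.37e-04; adjusted p = 0.860 with an estimated correlation). None of the 36 passed singly in limma or edgeR; 5 had an unadjusted p under 0.05 and 2 passed in DESeq2. The list's call was lost without untreated replicate 3 (camera adjusted p = 0.757) and without IL-36β replicate 1 (camera adjusted p = 0.615). This list was also lower in library set D and E than in A and B, by a median of -0.69 on the log2 scale. With the set as a term 8 members rose and all 36 were above 0, and the median was 0.41 within set A and B and 0.44 within set D and E. Ifitm3, which blocks viral entry, was 270 ± 58.6 FPKM in untreated and 430 ± 95.6 with IL-36β, and Isg15, a ubiquitin-like modifier, was 29.9 ± 11 and 44.6 ± 23.5.

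**Figure D2:**
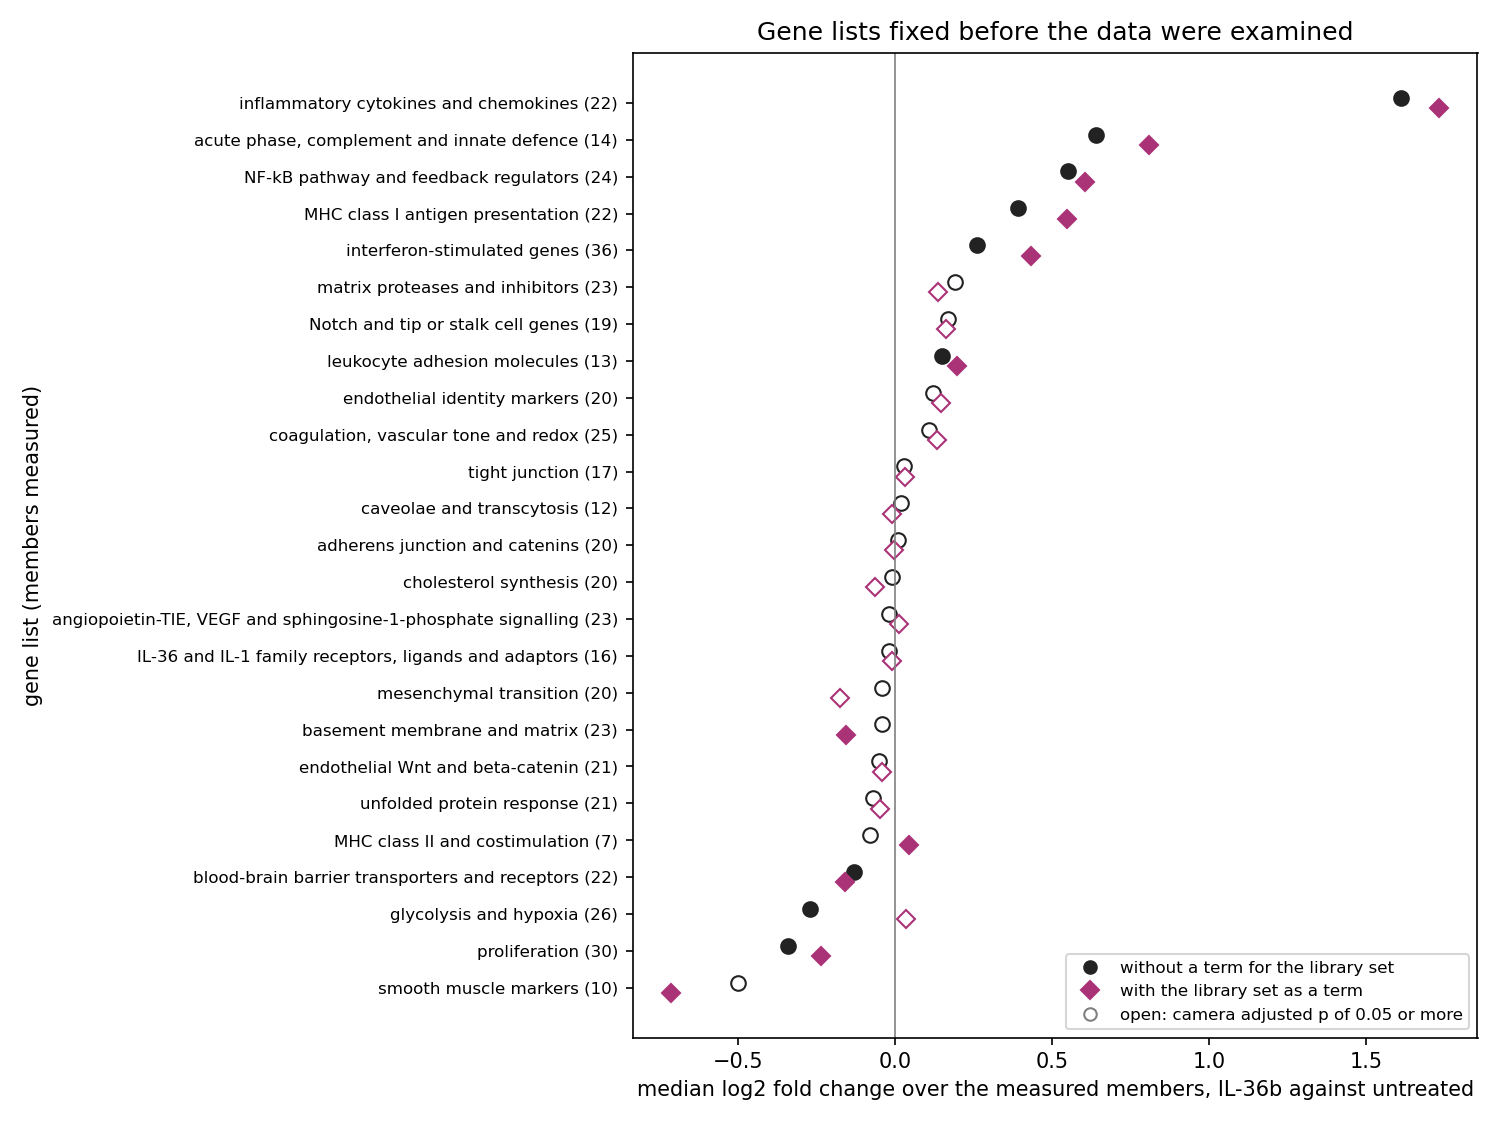
Median log2 fold change of the measured members of each of 25 gene lists, IL-36β against untreated, without (circles) and with (diamonds) the library set as a term; filled symbols have a camera adjusted p under 0.05. The cytokine and chemokine list lies highest at 1.61, and the glycolysis and hypoxia list moves from -0.27 to 0.03 when the set is a term.

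The series title concerns vascular stability and permeability, and no measured gene of the tight and adherens junction lists passed the threshold over all genes in limma or edgeR. Cdh5, which encodes VE-cadherin, was 956 ± 97.1 FPKM in untreated and 974 ± 135 in IL-36β cells, a fold of 1.02 with a 95% confidence interval of 0.79 to 1.31. Ocln had a fold of 1.02 (0.89 to 1.17), Tjp1 0.99 (0.80 to 1.23) and Pecam1 1.11 (0.84 to 1.46). Cldn5, the dominant claudin of the blood-brain barrier, was 157 ± 20.9 FPKM in untreated and 267 ± 85.4 FPKM in IL-36β cells, a fold of 1.65 (1.12 to 2.43) that missed the threshold (limma adjusted p = 0.378). Cldn5 was 1.70-fold higher within set A and B and 1.71-fold higher within set D and E, and DESeq2 on the recovered reads called it. The groups overlapped, at 180.7, 142.9 and 146.2 FPKM in untreated replicates 1 to 3 and 273.1, 179.3 and 349.9 FPKM in IL-36β replicates 1 to 3. The tight junction list had 17 measured members, none past the threshold in limma or edgeR, 3 at an unadjusted p under 0.05 and 1 in DESeq2 (median log2 fold change 0.03; camera adjusted p = 0.654). The adherens junction and catenin list had 20, none past the threshold in limma or edgeR, 5 at an unadjusted p under 0.05 and 3 in DESeq2 (median log2 fold change 0.01; camera adjusted p = 0.654), and Ptprb alone fell when adjusted over the list. Cldn1 and Cdh2, chosen after their values were seen, had folds of 0.53 and 0.57 that missed the threshold (limma adjusted p = 0.451 and 0.362), and DESeq2 called Cdh2. Vcl and Ptprb, which encode vinculin and the phosphatase VE-PTP, fell with the library set as a term; they were chosen after their values were seen.

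Regulators of vessel stability were given whatever their result. Tek, the angiopoietin receptor TIE2, was 9.92 ± 1.47 and 14.4 ± 2.80 FPKM, a fold of 1.43 (1.09 to 1.86; limma adjusted p = 0.362). Angpt2 was 937 ± 125 and 1273 ± 220 FPKM, a fold of 1.35 (1.02 to 1.80; limma adjusted p = 0.456). Plvap, a marker of fenestrated and leaky vessels, was 11.7 ± 3.30 and 10.5 ± 4.35 FPKM, a fold of 0.86 (0.49 to 1.52). The list of angiopoietin, VEGF and sphingosine-1-phosphate signalling had 23 measured members, none past the threshold in limma or edgeR, 4 at an unadjusted p under 0.05 and 1 in DESeq2 (camera adjusted p = 0.844). Of the caveolae and transcytosis list 12 members were measured, none past the threshold in limma, edgeR or DESeq2 and 1 at an unadjusted p under 0.05 (camera adjusted p = 0.698).

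**Figure D3:**
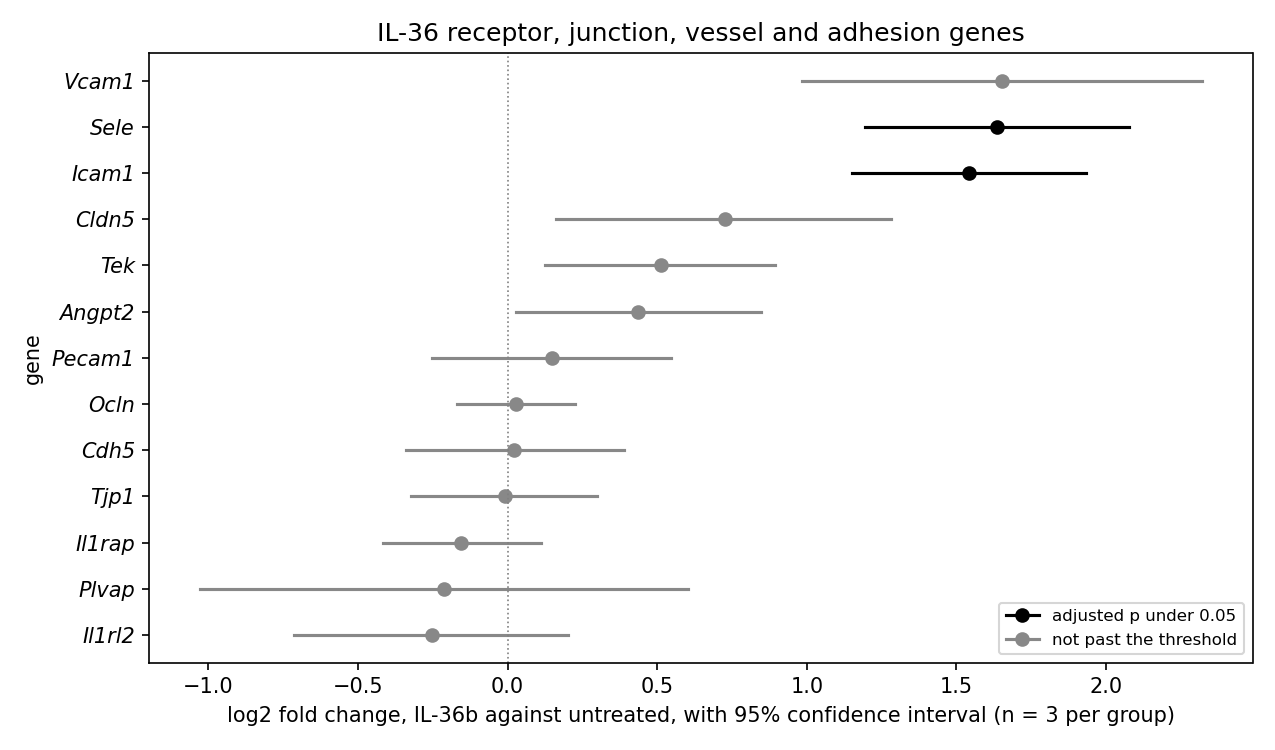
Log2 fold change of the 13 genes fixed in advance, IL-36β against untreated, with 95% confidence intervals from limma (n = 3 per group). Icam1 and Sele passed the threshold, and the intervals of Cdh5, Ocln, Tjp1 and Pecam1 include 0.

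Transporters and receptors of the blood-brain barrier were slightly lower as a list: 19 of 22 measured members had fitted fold changes below 0, with a median of -0.13 on the log2 scale (camera adjusted p = 0.00457; adjusted p = 0.200 with an estimated correlation). The median was -0.16 within set A and B and -0.13 within set D and E. No member passed in limma or edgeR; 2 had an unadjusted p under 0.05 and DESeq2 called 1, the anion transporter Slco1a4, which was 1.84 ± 0.353 and 0.644 ± 0.195 FPKM and which fell when adjusted over the list alone. Without a filter on low values the list's call was lost (camera adjusted p = 0.108). The most abundant members were Bsg, at 368 ± 75.2 and 335 ± 94.2 FPKM, and Slc2a1, the glucose transporter GLUT1, at 317 ± 89.0 and 226 ± 82.4 FPKM. Both were also lower in libraries D and E than in A and B, by 1.52-fold and 1.75-fold (limma adjusted p = 0.0307 and 0.0131).

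The receptor chains for IL-36 were expressed at low to moderate levels in both groups. Il1rl2 was 0.929 ± 0.261 FPKM in untreated and 0.690 ± 0.117 FPKM in IL-36β cells, and Il1rap was 5.98 ± 0.258 and 5.34 ± 0.690 FPKM; neither passed (limma adjusted p = 0.676 and 0.656). Of the 16 measured IL-36 and IL-1 family receptors, ligands and adaptors none passed over all genes in limma, 4 had an unadjusted p under 0.05, edgeR called 1 and DESeq2 called 2. Adjusted over the list alone 3 rose: Irak3, an inhibitor of IL-1 receptor signalling, Irak2, and Sigirr, a negative regulator of this receptor family (camera adjusted p = 0.674 for the list, whose median log2 fold change was -0.02 and mean 0.08).

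Proliferation genes were lower as a list, with 26 of 30 fitted fold changes below 0 and a median of -0.34 on the log2 scale (camera adjusted p = 2.77e-06; adjusted p = 0.748 with an estimated correlation). No member passed in limma or edgeR, 9 had an unadjusted p under 0.05, all lower, and 2 passed in DESeq2. The median was -0.22 within set A and B and -0.14 within set D and E. The most abundant members, Ccnd1 and Pcna, were 282 ± 11.3 and 356 ± 92.7 FPKM, and 33.9 ± 4.90 and 31.7 ± 3.79 FPKM.

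The glycolysis and hypoxia list was lower in the pooled comparison, with 23 of 26 fitted fold changes below 0 and a median of -0.27 on the log2 scale (camera adjusted p = 0.0232; adjusted p = 0.860 with an estimated correlation). This did not hold within the library sets, where the median was 0.08 in A and B and -0.07 in D and E, nor with the set as a term (median 0.03; camera adjusted p = 0.935). The list's call was also lost without untreated replicate 1 or 2 (camera adjusted p = 0.305 for each) and without IL-36β replicate 2 (0.515) or 3 (0.319). It was lost without a filter on low values too (camera adjusted p = 0.138). No member passed in limma, edgeR or DESeq2, and none had an unadjusted p under 0.05. Pgk1, a glycolytic enzyme, was 578 ± 135 and 519 ± 198 FPKM.

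The remaining endothelial lists did not pass. None of the 20 endothelial identity markers passed over all genes in limma or edgeR, 6 had an unadjusted p under 0.05 and 2 passed in DESeq2 (camera adjusted p = 0.654). Adjusted over that list alone Ptprb fell, and Ly6a, at 989 ± 188 and 1158 ± 136 FPKM, was abundant in both groups. Camera adjusted p was 0.249 for basement membrane and matrix, 0.249 for matrix proteases and inhibitors, 0.432 for Notch and tip or stalk cell genes, 0.654 for endothelial Wnt and β-catenin, and 0.685 for coagulation, vascular tone and redox. It was 0.673 for mesenchymal transition, 0.654 for the unfolded protein response and 0.929 for cholesterol synthesis. No member of these 8 lists passed over all genes in limma or edgeR. At an unadjusted p under 0.05 there were 3 matrix, 4 protease, 4 Notch, 2 Wnt, 3 coagulation, 5 mesenchymal, 2 unfolded protein response and 3 cholesterol genes, and DESeq2 called 3, 2, 2, 1, 1, 2, 0 and 0 of these lists. Adjusted over each list alone the matrix genes Nid1 and Fbln5 fell, the Wnt-list gene Sox7 rose, Adamts4 of the protease list rose while Timp3 fell, and Sod2 of the coagulation and redox list rose. The matrix genes Fn1 and Thbs1 were 1974 ± 295 and 1739 ± 327 FPKM, and 1433 ± 37.0 and 1033 ± 88.0 FPKM. With the library set as a term the basement membrane and matrix list was lower (median -0.16; camera adjusted p = 0.0150; adjusted p = 0.474 with an estimated correlation). The MHC class II and costimulation list was called higher with that term (camera adjusted p = 0.0266; adjusted p = 0.288 with an estimated correlation). Its median was only 0.05, and 4 of its 7 measured members were above 0. The 2 members called higher were Cd40 and Icosl, neither of them an MHC class II gene.

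Markers of other brain cell types were mostly near the detection limit. Of the lists, 3 of 12 pericyte, 2 of 12 fibroblast and leptomeningeal, 2 of 10 astrocyte, 2 of 15 microglia and macrophage, 1 of 10 oligodendrocyte and 2 of 10 neuron markers were measured, and none of them passed in limma, edgeR or DESeq2. Pdgfrb of pericytes was 2.63 ± 0.297 and 2.54 ± 0.743 FPKM, Col1a2 of fibroblasts 0.276 ± 0.279 and 0.799 ± 0.689, Gja1 of astrocytes 3.33 ± 0.453 and 3.32 ± 0.385, and Cd68 of macrophages 7.20 ± 0.427 and 7.58 ± 1.51. Cnp was 11.1 ± 1.09 and 13.1 ± 3.20 FPKM, and Tubb3 8 ± 4.65 and 15.3 ± 8.85. All 10 smooth muscle markers were measured, and Acta2, which encodes the smooth muscle actin, was 792 ± 483 FPKM in untreated and 536 ± 218 in IL-36β cells. None of the 10 passed over all genes in limma or edgeR, and 5 had an unadjusted p under 0.05 (camera adjusted p = 0.152). Adjusted over the list alone Myh11, Cnn1 and Actg2 fell, which DESeq2 also called, and Smtn rose. With the library set as a term the list was lower (median -0.71; camera adjusted p = 0.0147; adjusted p = 0.474 with an estimated correlation).

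The authors' deposited table lists 660 genes, 425 higher and 235 lower with IL-36β, all at an unadjusted p of at most 0.05 and all with the same adjusted p of 0.9987. Of these, 458 were tested here and 456 had the same sign; 17 of the 23 genes past the threshold are listed in the authors' deposited table. The authors' deposited table of enriched terms among genes higher with IL-36β is led by the response to molecule of bacterial origin, with 34 of 365 listed genes against 306 of 15819 background genes (the authors' adjusted p = 1.09e-10), and it gives cytokine activity for 22 of 360 genes (the authors' adjusted p = 2.01e-09). Both tables come from the same series and are no independent evidence; which libraries went into them is not settled by the sources used here.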

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

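The edgeR and DESeq2 tests and those with the library set as a term were chosen after the data were examined; the others in this part were planned. Main counts are 23 genes (21 higher, 2 lower), 2 fixed genes and 9 lists. Pseudocounts, an FPKM minimum of 1, quantile and median-ratio scaling, robust and weighted fits and protein-coding genes alone gave 21 to 34 genes, 21 to 23 of them shared with the 23. With no filter limma called 0 of 23998 genes (1751 at an unadjusted p under 0.05) and 0 fixed genes (5 unadjusted). TPM scaling gave 15 genes, all among the 23, and 1 fixed gene. The cause was not tested for either setting. Leaving out a library gave 2 to 8 genes, 0 to 2 fixed genes and 7 to 9 lists. Same-numbered libraries did not pair (correlations of deviations 0.21, -0.14 and 0.21): the replicate block by number gave 13 genes, 10 shared, and in edgeR 96. Same-letter libraries had correlations of 0.21 (A) and 0.28 (D), below the 0.39 of untreated 2 and IL-36β 1, which differ in letter. The replicate block by library letter gave 78 genes (67 higher, 11 lower), 19 shared, and in edgeR 507 (277 higher, 230 lower). Only letters A and D hold both groups, so these counts rest on few libraries. The edgeR test gave 37 genes, 20 shared, and DESeq2 269 (173 higher, 96 lower), 21 shared, with 4 fixed genes, as did edgeR with the letter block (4). The set term gave 102 genes (85 higher, 17 lower) in limma, all 23 among them, and 252 (171 higher, 81 lower) in edgeR. No list passed with an estimated correlation, without (0) or with (0) the set term; fry called 3 (cytokines and chemokines, NF-κB, barrier transporters). The glycolysis and hypoxia list turned to a median of 0.03 under the letter block (adjusted p = 0.942) and under the set term (0.03; 0.935, 0.962 with an estimated correlation, 0.939 in fry; without it camera gave 0.0232). Sign agreement with the authors' table was 99.6% and was 100% with a minimum of 1, quantile scaling and the set term; without a library it was 98.9 to 100%, lowest without IL-36β replicate 1. For single named genes no sign change involved a call; 178 values lost and 25 gained a call, and 15 uncalled values changed sign by more than their SE. Depth limits genes such as Mir194-1 and Gm11382, with 11 and 13 reads in all.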

Other observations

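All tests in this part, and the genes named, were chosen after the values were seen. Of the 17 genes that limma called lower with the library set as a term, 6 are given here, and no list was tested for them as a group. Clec14a, an endothelial lectin, had a fold of 0.55 (95% confidence interval 0.475 to 0.638; limma adjusted p = 0.0147), Ptprb 0.626 (0.532 to 0.736; 0.0414) and Timp3, a metalloprotease inhibitor, 0.624 (0.531 to 0.734; 0.0403). Fat1, an atypical cadherin, had a fold of 0.474 (0.368 to 0.611; 0.0401), and Vcl and Flnc, which link actin to adhesions, 0.634 (0.550 to 0.730; 0.0308) and 0.572 (0.489 to 0.670; 0.0224). None of these 6 genes passed in the pooled limma test. Zbp1, a sensor of nucleic acids, was 3.27-fold higher with the set term (2.43 to 4.40; limma adjusted p = 0.0147).

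The library sets differed in genes of the response to low oxygen and, as lists, in inflammatory and antigen presentation genes. In a limma model with treatment as a term, Slc16a3, a lactate exporter, was 9.08-fold lower in libraries D and E than in A and B (adjusted p = 7.03e-04), Egln3 5.77-fold (7.03e-04), Ak4 5.74-fold (0.00191) and Vegfa 3.26-fold (0.00259). Of 26 glycolysis and hypoxia genes 17 were lower in D and E and none was higher (camera adjusted p = 1.07e-25; adjusted p = 0.134 with an estimated correlation), as were 12 of 36 interferon-stimulated genes (camera adjusted p = 2.60e-26; adjusted p = 0.134 with an estimated correlation). The lists that were higher with IL-36β were also lower in D and E: cytokines and chemokines (19 of 22 below 0; camera adjusted p = 6.36e-07; adjusted p = 0.134 with an estimated correlation), acute phase (13 of 14; 2.13e-06; 0.134), MHC class I (19 of 22; 1.82e-08; 0.134), NF-κB (16 of 24; 8.17e-04; 0.427) and leukocyte adhesion (11 of 13; 0.0241; 0.540).

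Inflammatory genes were higher with IL-36β. Time in culture was not tested as a source, since the titles give no time for untreated cells. If the numbers in the library names (A0, B0 and D0, and A24, D24 and E24) are hours, time and treatment coincide in all libraries. A difference between library sets is argued against as the whole source for the cytokine and chemokine list, which was fixed in advance. Its median log2 fold change was 1.53 within A and B and 1.85 within D and E. All 23 called genes stayed called with the set as a term, but the pooled test had favoured genes with little spread between the sets. Added microglia and macrophages are argued against too: C1qa, C1qb, C1qc, Tyrobp and Trem2, abundant in these cells, had 0 reads in the IL-36β libraries. Col1a1, Col1a2 and Col3a1 of fibroblasts rose by 0.965 FPKM together, from 0.799 to 1.76 FPKM, in cultures that had been under puromycin. The 5 called cytokine genes rose by 67.8 FPKM, but they were picked as called in these same libraries, so that comparison cannot decide. The collagen sum was 0.487, 0.615 and 1.29 FPKM in untreated and 0.278, 1.64 and 3.38 FPKM in IL-36β replicates 1 to 3. Added fibroblasts are thus argued against for IL-36β replicate 1 only, the IL-36β library of set A and B. The 10 splits of the 6 libraries are too few for a share under 0.05. At least 23 genes were called by 2 splits, the real one with 23 and 1 other with 136, and the next called 1. The split with 136 is that of the library sets. Those sets were picked from these same values and no label gives a batch, so that split cannot be set aside on this ground. The smooth muscle marker Acta2 was abundant and the marker list had a median of -0.71 on the log2 scale in the model with the set term, and how much of the response came from smooth muscle cells or from the endothelium stays open.

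Of the genes that differed at least 4-fold, 12 missed the threshold in the pooled limma test, Lcn2, Cxcl1 and Ccl2 among them, which DESeq2 called. With the set as a term 9 of the 12 passed, all higher, so a difference between the library sets may be what widened their spread. Untreated replicate 3 alone cannot be told apart from its set here: without it 2 of the 12 passed, Ccl2 (higher) and Gapdh (lower), with fewer libraries. The median of the 12 genes in D and E lay 1.53 below A and B on the log2 scale among untreated and 0.78 below among IL-36β libraries. Gapdh stood at 30.5, 25.2 and 1.04 FPKM in untreated and 2.28, 1.24 and 1.01 FPKM in IL-36β replicates 1 to 3. It did not pass with the set as a term (limma adjusted p = 0.357). Whether donors, days or cultures differ between the sets was not tested, as the labels give none.

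The lower glycolysis and hypoxia genes may come from the uneven split of the library sets over the groups. With the set as a term the list's median log2 fold change moved from -0.27 to 0.03. An effect of IL-36β in each set is argued against: 6 of 26 members were lower within both sets, where signs independent between the sets give 6.5. Over all genes tested, 63.6% had the same sign within both sets. The list's median was 0.08 within A and B and -0.07 within D and E. What made the sets differ stays open.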
